A study of Solanum tuberosum with 6 samples.

How the data were processed

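RNA from seed tubers was sequenced in 3 libraries after poly(A) selection, and DNA from seed tubers in 3 libraries after bisulfite conversion, all with paired-end reads of 150 bp, per the labels' protocols. The submitters' processing notes name TopHat2 2.1.0, a spliced aligner, and BSMAP 2.9, a bisulfite aligner, with no further settings. The genome build, and the program that computed the expression values, are not given in the sources used here; the gene IDs carry the suffix v4.03. The expression values are FPKM as deposited by the authors, named so in the file header, in 1 column for the whole series. Which of the 3 RNA libraries entered that column, and how, is not given in the sources used here, so it was treated as the authors' value for the RNA group, with no SD and no n. The methylation calls of the DNA libraries were not analysed here.

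The RNA samples formed 1 group and the DNA samples another, since within each kind every label except a number is the same; nothing in the labels says whether they came from separate plants or tubers. There was no contrast of conditions to test. Before the data were examined, 5 kinds of result had been planned: genes detected, agreement between libraries, genes that differ between libraries, the level of 22 gene lists (storage proteins, proteinase inhibitors, starch and sucrose metabolism, photosynthesis, DNA methylation and others), and the share of expression in the highest genes. With 1 value per row, agreement and differences between libraries could not be computed. The gene lists were patterns on gene names. None of the gene IDs (0 matches) occurred in the reference list of 32873 potato genes of assembly SolTub_3.0, so none of the 22 lists was run and no list has a result. The rule for named genes, fixed beforehand, was to name the 10 highest genes, list members and genes that vary between libraries, and to name at most 2 IDs per part where IDs could not be paired with names. The 2 highest IDs are therefore given.

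FPKM values were used as deposited, with each row kept separate where an ID had several rows. Rows at 1 FPKM or more were counted, with 0.1, 0.5 and 5 FPKM and any value above 0 as alternatives. Shares are of the summed FPKM of the listed rows. Rows with an FPKM identical to another row's were counted and compared with 100 tables in which each value was multiplied by a random factor (SD 0.05 on the natural log scale) and rounded to 6 significant digits. A multiple of a shared value was taken as present when a row matched it within a relative tolerance of 6e-06. Correlations between rows used log2(FPKM + 1), with 0.1 and 0.01 as other pseudocounts, and are across genes; their two-sided permutation tests drew 100000 permutations, with Benjamini-Hochberg adjustment over 7 kinds of pair. No interval or detection limit from counts was computed, because the depth is unknown.

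The procedures were tested on simulated data that started from 16250 rows. In the simulations of shared values, rows that fell under 0.5 FPKM were left out. For neighbouring rows simulated with a correlation of 0.2, the 50 simulated tables gave a mean of 0.200 (SD 0.0181 over tables, 2129 pairs), and with no correlation a mean of 0.00119. The second value of each pair was drawn from the first, so this checked only the calculation of r. It did not test the effect of pairs that share a row, or the permutation test. In a table simulated from whole fragments at 1 scale, the double of a shared value was present for 39.0%, against 4.94% for the control multiple; in a table simulated as the mean of 3 libraries of different depth, both shares were 2.83%. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots Matplotlib 3.10.9.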

Results

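Potato (Solanum tuberosum) was profiled in seed tubers, the tubers kept for planting, of the cultivar Pacific. The series held 6 samples, of which 3 were RNA libraries for expression and 3 were bisulfite-treated DNA libraries for methylation. Every sample carried the same tissue and the same cultivar, and the samples of each kind were told apart by a number alone. No treatment, time point or second tissue was named, so the design contained no contrast between conditions. Expression was given as a single FPKM value per row (fragments scaled to gene length and to the total of mapped fragments), as deposited by the authors, in 1 column that names no library. Which RNA libraries entered it is not given in the sources used here. No value could therefore be given per library, no error between replicates could be computed, and each number below is the authors' value without SD or n. Methylation levels were not analysed here. The number of reads behind each value is unknown.

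A small number of genes held much of the summed FPKM. The highest value, 183788 FPKM, belonged to PGSC0003DMG402017090.v4.03 and made up 10.5% of the summed FPKM of the table. PGSC0003DMG402008909.v4.03 came second at 91435.5 FPKM, 5.22% of the sum, so that the first gene stood 2.01-fold above the second. The genes ranked 3 to 10 ranged from 59311.4 down to 11542 FPKM, and these 10 genes were the only rows at 10000 FPKM or more. Together they held 26.9% of the summed FPKM. The 100 highest rows held 49.0%, and 109 rows were enough to reach 50%. The 1000 highest rows held 77.1%, and 3099 rows reached 90%. When the highest gene was left out, the next 10 genes held 18.9% of what remained. As FPKM divides by gene length, these shares are of transcripts by relative abundance and not of reads. Gene lengths were not used and read counts are unknown, so how far length shaped the highest values was not tested. The IDs of the genes ranked 8 and 9 carried numbers above 34000, a range treated below. Neither the table nor the reference list used here pairs the gene IDs of the table with names, so what the highest genes encode is not stated. Their genome positions were not used here.

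**Figure D1:**
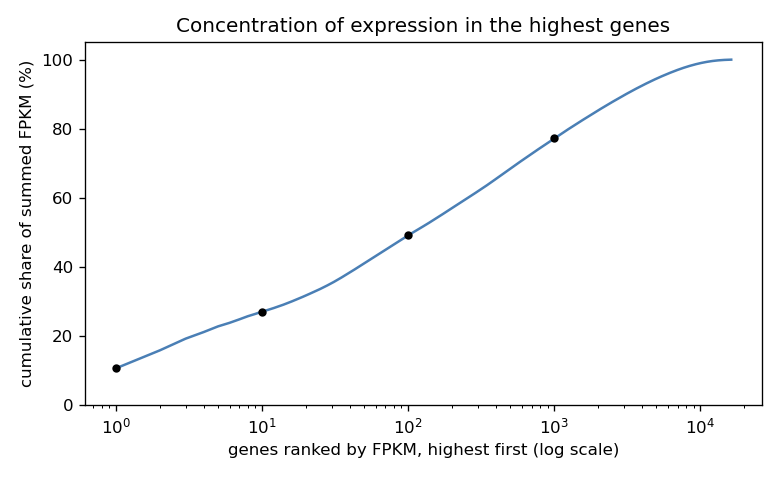
Cumulative share of the summed FPKM (vertical axis, percent) over genes ranked from the highest FPKM (horizontal axis, log scale), with points at ranks 1, 10, 100 and 1000. The points lie at 10.5%, 26.9%, 49.0% and 77.1%.

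The listed rows spanned a wide range of levels. The table listed 16250 rows with a median of 12.2 FPKM, and the middle of the distribution ran from 3.37 FPKM at the 25th percentile to 40.1 FPKM at the 75th. The 95th percentile was 268 FPKM and the 99th was 1271 FPKM. Of all rows, 14998 (92.3%) were at 1 FPKM or more, 11114 (68.4%) at 5 or more and 8856 (54.5%) at 10 or more. At 100 FPKM or more there were 1991 rows (12.3%), and at 1000 or more there were 210 (1.29%). The 7394 rows under 10 FPKM contributed 1.57% of the summed FPKM. No row lay under 0.5 FPKM and the lowest was 0.500045 FPKM, while 344 rows lay between 0.5 and 0.6 FPKM and 250 between 0.6 and 0.7. The table thus ended at 0.5 FPKM. A gene that it does not list may have any lower value, including 0. It may also be absent for another reason, since which genes were quantified is not known here.

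**Figure D2:**
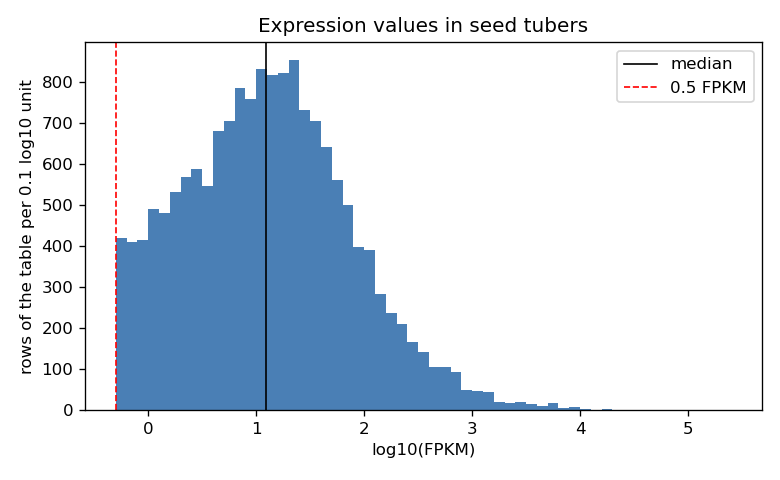
Histogram of log10(FPKM) (horizontal axis) with the number of rows per 0.1 log10 unit (vertical axis). The solid line marks the median of 12.2 FPKM and the dashed line marks 0.5 FPKM, under which no row was listed.

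The rows were described by 16091 different gene IDs. For 153 of these IDs the table gave more than 1 row, 312 rows in all, each with its own FPKM. Among the 148 IDs with exactly 2 rows, the higher value was a median 2.22-fold above the lower. For comparison, IDs listed once and with the digit 0 before their 6-digit number were taken in adjacent rows. Their values differed by a median 4.05-fold where the numbers were 1 apart, and 6.81-fold where they were over 1000 apart. The digit that precedes the 6-digit number of an ID was 0 in 14069 rows, 1 in 1076 rows, 2 in 987 rows and 3 in 101 rows, with medians of 12.3, 10.8, 12.6 and 10.2 FPKM. The remaining rows had the digit 4 (15 rows, median 2.97 FPKM) or 5 (2 rows, median 53.9 FPKM). Both of the highest genes had an ID with the digit 2.

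Many rows held the same value as another row. In 1877 rows (11.6%), the FPKM was identical in all its printed digits to that of at least 1 other row, and 709 different values were shared in this way. The value 6.28063 FPKM occurred in 12 rows. When every value was moved at random and rounded to 6 significant digits, 100 such tables held between 128 and 214 rows with a shared value. Shared values made up 26.7% of the rows from 0.5 to under 1 FPKM, 15.0% from 1 to under 10, 8.29% from 10 to under 100 and 2.81% from 100 to under 1000, and none of the 210 rows at 1000 FPKM or more. The highest shared value was 609 FPKM. The double of a shared value was present in some row of the table for 36.8% of the shared values, the triple for 29.9% and the 4-fold value for 24.7%. Between the 709 shared values themselves, 106 pairs stood at the ratio 2, 64 at 3 and 43 at 4. For 10 control multiples from 1.91 to 2.09, the matching share was between 2.12% and 4.09%. These figures describe rows of 1 table, and genes are not independent replicates.

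**Figure D3:**
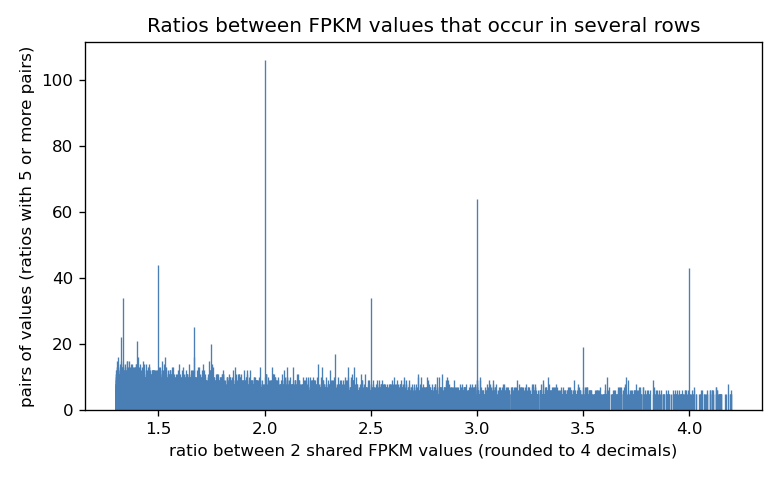
Ratios between pairs of FPKM values that occur in several rows (horizontal axis, from 1.3 to 4.2, rounded to 4 decimals) and the number of pairs at each ratio (vertical axis), for ratios with 5 or more pairs. The highest lines stand at 2 (106 pairs), 3 (64 pairs), 1.5 (44 pairs) and 4 (43 pairs).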

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

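The alternatives that sum rows of the same ID, leave out the highest gene or leave out rows with a shared value, the top 100 share with capped values, and all alternatives for neighbouring rows and for high ID numbers were chosen after seeing the data. The number of rows at 1 FPKM or more, 14998, became 16250 at 0.1 FPKM, at 0.5 FPKM or above 0, which differ in nothing because the table ends at 0.5 FPKM, and 11114 at 5 FPKM. With rows of the same ID summed, 14856 IDs were at 1 FPKM or more. The share of the 10 highest genes, 26.9%, fell to 8.27% with values capped at the 10th highest gene and to 18.9% without PGSC0003DMG402017090.v4.03, and was 27.4% without rows that share a value. The share of the 100 highest, 49.0%, was 36.0%, 43.2% and 49.9% under the same alternatives. These follow from the construction of each alternative. Summing rows of the same ID left both shares as they were. The planned omission of each replicate, the rescaling of libraries and the alternatives for agreement between libraries, for differing genes, for gene lists and for shares without list members were not run, since the table has 1 value column and the sources used here pair its IDs with no names. The depth is unknown, so what it limits could not be computed.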

Other observations

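The patterns below were found in the data, and the tests on shared values, on ranks and on ID numbers were chosen after related values had been seen; the tests without shared values and without pairs of nearly equal level were written before their results.

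Adjacent rows with consecutive ID numbers had related levels. For 2129 pairs of adjacent rows whose ID numbers differ by 1, Pearson's r across genes on log2(FPKM + 1) was 0.21 and Spearman's rho 0.20 (permutation p = 1e-05 each, the smallest that 100000 permutations can give, 2e-05 after adjustment over 7 kinds of pair). For the 4552 pairs with consecutive numbers that were not adjacent rows, r was -0.01 (permutation p = 0.563, adjusted 0.657), and for 2689 adjacent rows whose numbers differ by over 1000 r was 0.00489 (p = 0.8, adjusted 0.8). Adjacent rows with numbers 2 apart gave 0.06 (permutation p = 0.0463, adjusted 0.0648). Numbers 100 apart, in rows adjacent or not, gave -0.04 (permutation p = 0.00855, adjusted 0.015), with rho -0.03 (permutation p = 0.0599, adjusted 0.105). All kinds of pair named so far used only IDs with the digit 0 and a single row. The differences between these kinds of pair were not tested, and a row can belong to more than 1 pair. The pattern was also found in these same data. The permutation tests do not allow for that, or for rows shared between pairs. Among IDs with the same 6-digit number, r was 0.31 over the 669 pairs with the digits 1 and 2, and it was 0.66 over the 148 IDs with 2 rows (permutation p = 1e-05, adjusted 2e-05, for both).

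The correlation of adjacent rows with consecutive numbers was weighed against 3 explanations. Repeated values do not account for it. Without rows that share a value, r was 0.22 over 1753 pairs, above the highest of 1000 permuted tables (0.08). Rows of low precision whose value is not repeated stayed among these pairs, so low precision beyond repeated values was not tested. A few very high genes do not account for the correlation either, since the rank correlation of 0.20 was above the highest permuted value of 0.07. For a gene split into 2 models, or reads counted for both, the values went against the prediction, as pairs within 0.25 on the log2 scale were 7.89% of pairs against a median of 7.19% and a highest value of 9.16% in permuted tables, and without them r was 0.16 against at most 0.02; but even the 2 rows of 1 ID differed by a median 2.22-fold, so that window was too narrow to find such pairs and the explanation stays open. Whether the pairs are neighbours on a chromosome, tandem copies, overlapping genes or parts of 1 gene remains open, as gene positions and sequences were not used here, and no biological explanation was tested.

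The values shared by several rows were weighed against 3 explanations. Rounding to 6 digits gave at most 214 such rows against the 1877 found. Whole numbers of fragments divided by gene lengths at a single scale may account for them, because the double of a shared value was present for 36.8% of values and for at most 4.09% at control multiples. For a mean over libraries scaled separately to different depths, the measure named in the prediction decided nothing: the most frequent ratio that is not a simple fraction, 1.3254, occurred 22 times against 44 for the ratio 1.5, and in simulated tables such ratios had 4 pairs for a mean of 3 libraries and 57 for 1 scale. In the table simulated for such a mean, the double was present for 2.83% of shared values, equal to the control. That share was 39.0% at 1 scale and 36.8% in the deposited table. Pairs at the ratios 2 and 1.5 numbered 1 and 0 for the mean, 187 and 177 at 1 scale, and 106 and 44 in the deposited table. The table simulated at 1 scale thus had nearly as many pairs at 1.5 as at 2, a balance that the deposited table did not have. Such counts also depend on how many values are shared, which was not matched between the tables. The simulations rest on assumed gene lengths and depths, with 1 table each. Lower depths, at which a row may hold fragments from only 1 library, were not simulated, so the share of doubles does not decide against a mean. Which libraries entered the column, and whether it is an average, therefore remains open, and a biological explanation was not tested.

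Listed IDs numbered from 34000 up to the highest, 47346, were sparse and low. They made up 405 listed rows with a median of 4.18 FPKM, against 12.6 FPKM for the 15845 listed rows with lower numbers. The ratio was 0.332 (95% bootstrap interval over genes 0.268 to 0.390, two-sided permutation p = 1e-05, the smallest that could be given). The split was chosen after related values had been seen, and neither the interval nor the permutation test allows for that choice. About 30.2 numbers were listed per 1000 in this range, against 438 per 1000 under it. The ratio and its test cover only listed rows, none of them under 0.5 FPKM, and say nothing of unlisted numbers. The ratio was 0.552 with the split at 32000, 0.278 at 36000 and 0.367 without rows that share a value. Yet 6 of these rows were among the 100 highest, where 2.49 would fall by their share of rows, a difference that was not tested. At FPKM matched in 10 classes, shared values were 8.01 percentage points more frequent among these IDs (95% interval 4.35 to 11.8). The permutation p was 0.0001, the smallest that 10000 permutations can give. Levels may still differ within a class. Values resting on few fragments, as short gene models would give, may account for this if the column holds whole fragments at 1 scale, which stays open. Lengths were not used here, and a biological explanation was not tested.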
